A study of Homo sapiens with 29 samples.

How the data were processed

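DNA methylation and DNA copy number were measured together with DARE, an assay based on restriction enzymes. Per the labels' protocols, HpaII first cuts CCGG sites that are unmethylated and a tag is ligated to those ends. MspI and NlaIII are then used, and MspI, which cuts CCGG whether methylated or not, opens the remaining CCGG sites. These receive a different tag, so that each CCGG site yields unmethylated (U) and methylated (M) tags. The libraries comprised HepG2, a hepatocellular carcinoma line, and K562, a chronic myeloid leukaemia line, each with 2 libraries from 100 ng and 2 from 1 ng of bulk DNA and with 10 single cells. There was also 1 library from 100 ng of embryonic stem cell (ESC) DNA, which the labels describe as a reference for copy number. Per the labels' protocols, single cells were stained with Calcein-AM and isolated into tubes, libraries were amplified by PCR and fragments were selected by size.

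Each of the 29 deposited files lists CCGG sites of the hg38 build with, per the labels, a methylated fraction (0 to 1) and the number of tags (counts, U plus M) that the authors obtained at the site. The deposited fraction times the deposited count lay within 0.0013 of a whole number at each of the 21881614 site entries, so M and U counts were taken as that product and its complement. Each listed site had at least 1 tag, so a site without tags was not listed. UMI-tools 0.5.4, cutadapt 1.5 and Bowtie2 2.3.4.1 were used, per the submitters' processing notes, which give neither their roles nor their order. Whether tags sharing a molecular identifier were collapsed before deposit is not given in the sources used here, so binomial and Poisson intervals cover counting error only.

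Nuclear sites comprised chromosomes 1 to 22, X and Y, and numbered 1949774 over all libraries. Bulk libraries of HepG2 held 4978203 to 7709837 nuclear tags, those of K562 7505119 to 8067412 and the ESC library 11971635. Single cells held 352732 to 1515793 tags. At these depths a bulk library had a mean of 3.51 to 6.34 tags per listed site and a single cell a median of 1, so sites were summed over regions. Methylation levels are percent M tags among U and M tags. Mitochondrial sites were kept apart, and their M share was used as a check of digestion: a corrected level was computed as (level - m)/(1 - m), with m the mitochondrial M share as a fraction.

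Gene coordinates came from a RefSeq gene table for GRCh38.p14, used without a genome sequence and without gene strand. The planned promoter, set around a transcription start, was therefore replaced by the end of a gene that was dense in CCGG sites. A gene end qualified when at least 4 sites seen in any library lay within 1000 bp of it and these were at least 2 times as many as at the other end. The window ran from 1000 bp outside to 500 bp inside the gene. Of 19829 genes considered, 11531 had such an end. Orientations of 175 genes were entered from general knowledge, 117 of these had a dense end, and it was the known start in 110 (94.0%). The 7 others were left out, as were 153 protein-coding genes on other scaffolds. A dense end can thus be the 3' end of a gene or the start of a neighbour. Repeats and CpG islands were replaced by classes of sites with 0, 1 to 2, 3 to 5 or 6 or more other CCGG sites within 500 bp. Arms were split at approximate hg38 centromere positions, entered from general knowledge. Coordinates are 1-based.

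Methylation of gene ends and of 1 Mb bins was compared with a quasi-binomial logistic model of M and U tags with cell line and input amount as terms. It used an F test, a Pearson dispersion moderated across regions with limma 3.58.1 and kept at 1 or above, and Benjamini-Hochberg adjustment. Gene ends needed 10 tags in each of the 8 bulk libraries and were called at an adjusted p below 0.05 with a difference of at least 25 percentage points between means of libraries. Bins needed 100 tags and 10 points. Copy number was compared with edgeR 4.0.16, a quasi-likelihood test with TMM normalization on tags per 1 Mb bin with at least 50 tags in each library, called at an adjusted p below 0.05 and a log2 difference of at least 0.3. Arm copy number was the log2 of an arm's tag share over that in ESC, centred on the median autosomal bin, with a threshold of 0.25. Arms of X were not compared with ESC, and Y was not reported. Single values per library were compared with exact permutation tests. All tests were two-sided. Single cells of a line are not replicates of it, so no test between the lines was made from cells. ESC, with 1 library, entered no test and was listed where a gene end with at least 50 tags differed by at least 50 points from the mean of both lines. Nothing in the labels says that replicate libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

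The groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The lists were 12: hepatocyte, erythroid and blood cell, pluripotency, imprinted, tumour suppressor, cancer-testis and germline, HOX, clustered protocadherin, developmental transcription factor, KRAB zinc finger, housekeeping, and stromal and other cell type genes. All 590 entries matched a gene. Enrichment of called members was tested per direction with Fisher's exact test against the other tested gene ends, with Benjamini-Hochberg adjustment over lists and directions. Named genes were the 8 protein-coding genes with the largest difference in each direction among called ends with at least 20 tags in each library and no overlap between the lines. From each list came the 3 called members of smallest adjusted p or, with none called, the 2 with most tags. For input amount the rule took the 3 largest called in each direction. For ESC it took the 4 largest in each direction, with POU5F1, NANOG, LIN28A and DPPA4 where measured. For copy number it took arms past 0.25, the 5 bins with the largest difference per direction, merged when adjacent, and the bins holding BCR, ABL1, CDKN2A and MYC. Some items that the rule takes are not reported here.

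Cells were compared with bulk DNA by correlation across 1 Mb bins (log2 tags over ESC) and across gene ends with at least 3 tags in the cell. To look for tags of the other line, 100 kb windows with at least 100 ESC tags were listed where bulk DNA of a line held under 0.1 of the ESC level and the other line over 0.3. For K562, those on chromosome 9 were kept. In addition, the tag profile of each cell over 2737 autosomal 1 Mb bins was fitted by least squares as a mixture of the 1 ng bulk profiles of both lines, with 2000 bootstraps over chromosomes. Tags in the K562 windows were compared between sites at or above and below 50% methylation in HepG2 bulk DNA (at least 5 tags), with 2000 bootstraps over windows. Relations across cells used permutation tests with 100000 resamples, adjusted over 9 relations, 3 of them added after the data were seen.

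Models were tested on simulated data with 200 changed regions. For gene ends between the lines, 39% of changes of 30 points and 95% of changes of 60 points were recovered, and for input amount 45% and 99%. For bins, 99% of changes of 15 points and 100% of log2 copy number changes of 0.4 were recovered, with 0 false calls in each. The spread between simulated libraries was set by hand and not estimated from these libraries. Regions other than the 200 did not change, whereas most 1 Mb bins differed between the lines, so recovery in the data can differ. Alternatives covered tag minima, windows, bin sizes, limma, edgeR with a methylation design, DESeq2 1.42.0, covariates, replicate blocks, subsets and each bulk library left out. Whole gene loci, with and without overlapping ones, 1 Mb bins for input amount, levels corrected by mitochondrial sites, tags per observed site, shared sites for single cells and omission of K562 cell 7 were added after seeing the data. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used.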

Results

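CCGG sites were profiled in 29 libraries: 4 bulk libraries each of HepG2 and K562, 10 single cells of each line and 1 bulk ESC library. The series examines whether methylation and copy number can be read from the same small amount of DNA, down to 1 cell. Bulk libraries covered 1245799 to 1484613 nuclear sites, and 817992 sites had a tag in all 8 HepG2 and K562 bulk libraries. The 2 replicates of each line and amount had chi-square values per degree of freedom of 1.12, 1.26, 2.23 and 1.32 over 1 Mb bins, so none agreed within the noise of independent tags, though copies of the same molecule would also raise these values. Each was counted as its own library, as labelled. Between replicates, methylation of sites with at least 10 tags correlated with Pearson's r of 0.956 to 0.963 across sites, which are not independent of each other.

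HepG2 DNA was more methylated than K562 DNA, and the gap was large in gene bodies and between genes and small at CCGG-dense gene ends. The methylation level was 55.9% ± 2.04 in HepG2 and 35.9% ± 1.30 in K562 (SD, n = 4 each), and all 4 HepG2 libraries lay above all 4 K562 libraries. In gene bodies the means were 67.9% and 47.0%, between genes 43.7% and 23.9%, and at gene ends 27.4% and 24.004%. Sites with 0 other CCGG sites within 500 bp differed by 21.3 points, and sites with 6 or more by 10.8. The difference in the level, 19.97 points, had an exact permutation p of 0.0286, the smallest that 4 against 4 can give, and each class had the same adjusted p of 0.0286. The gap of 3.44 points at gene ends was 2.61 points with sites weighted equally (exact permutation p = 0.171), which ended that call. In the ESC library, measured the same way, the level was 96.1% (exact binomial interval 96.08 to 96.11) and gene ends stood at 43.4%.

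**Figure D1:**
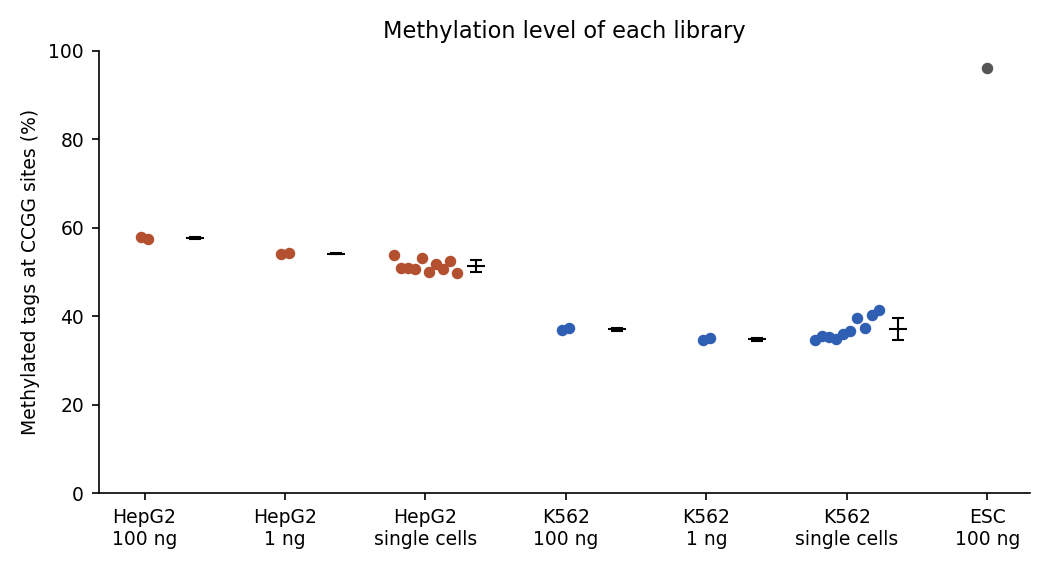
Methylation level (percent M tags) of each library, with the mean and SD of each group; bulk libraries and single cells of HepG2 and K562 are shown beside the ESC library. Bulk HepG2 averaged 55.9% and bulk K562 35.9%, and cells averaged 51.4% and 37.1%.

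Across 1 Mb bins the lower methylation of K562 covered most of the genome, with a small set of regions going the other way. The bin of chromosome 3 from 188000001 to 189000000, which holds LPP and TPRG1, stood at 89.4% ± 1.18 in HepG2 and 5.40% ± 0.454 in K562 (SD, n = 4), with 98.5% in ESC. Other bins high in HepG2 held PLCB1 on chromosome 20 (82.9% against 9.84%) and KL, STARD13 and RFC3 on chromosome 13 (85.8% against 13.5%). In the other direction, the chromosome 8 bin from 105000001 to 106000000 with ZFPM2, a cofactor of GATA transcription factors, stood at 30.04% in HepG2 and 72.4% in K562. Bins with TCF4 on chromosome 18 (24.5% against 54.4%) and with EPYC, KERA, LUM and DCN, a cluster of small proteoglycan genes on chromosome 12 (29.3% against 56.7%), were also higher in K562. The chromosome 11 bin with the beta-globin genes HBB, HBD, HBG1, HBG2 and HBE1 was higher in K562 as well (33.8% against 46.6%). Named methylation bins were chosen after their values were seen. Of 2875 bins tested, 2429 differed, 2390 higher in HepG2 and 39 higher in K562, and median bin levels were 50.5% in HepG2, 25.09% in K562 and 97.0% in ESC.

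At CCGG-dense gene ends, 270 were more methylated in HepG2 and 141 in K562, while 936 lay below 20% in both lines. The end of TMEM176A (chromosome 7, 150799769 to 150801269) was at 90.1% ± 6.69 in HepG2 and 12.4% ± 8.03 in K562 (SD, n = 4; limma-moderated adjusted p = 0.000160). That of RBM23, which encodes an RNA-binding protein (chromosome 14, 22918649 to 22920149), was at 97.49% ± 1.15 and 20.96% ± 8.96 (adjusted p = 9.88e-05). Also higher in HepG2 were the ends of SLC41A3, a magnesium transporter gene (84.7% against 9.94%), DCAF6 (83.6% against 30.7%), PPM1G (75.3% against 21.99%), MYO7B, an unconventional myosin of brush borders (65.7% against 8.65%), LBHD1 (55.3% against 4.29%) and CNTN2 (52.4% against 5.13%). By general knowledge of its orientation, the PPM1G window lies at the 3' end of that gene. Only 6 genes met the rule in the other direction. TUBB1, the beta-tubulin gene of platelets (chromosome 20, 59015438 to 59016938), was at 56.8% ± 9.06 in HepG2 and 97.9% ± 2.44 in K562. ZBED4 (29.3% against 66.9%), SLC6A6, a taurine transporter gene (21.3% against 58.2%), GINS2, a DNA replication gene (2.62% against 33.99%), LONP2, a peroxisomal protease gene (1.25% against 33.8%), and TMEM275 (1.95% against 32.8%) followed. In windows of 2000 bp either side GINS2 (-17.8 points) and TMEM275 (-21.4 points) fell short of the minimum difference and were not called. Over whole loci RBM23, DCAF6, PPM1G, CNTN2, TUBB1, ZBED4, SLC6A6, LONP2, GINS2 and TMEM275 were not called.

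The 411 calls were 19.3% of the 2131 gene ends tested, and 772 had an unadjusted p below 0.05. Over all 2131 ends, 587 (27.5%) showed no overlap between the 4 libraries of each line, which chance gives in 2.86% of ends. The median gene end was at 17.72% in HepG2 and 13.5% in K562. With the 100 ng libraries alone 0 of 3453 ends were called by the same model and 678 had an unadjusted p below 0.05 (smallest adjusted p 0.166), with the 1 ng libraries alone 0 of 3394 and 626 (0.194). These runs had 2 libraries per line. Even TMEM176A, 81.2 points apart at 100 ng and 74.3 at 1 ng, had only these smallest adjusted p-values, so 0 calls there do not show that the lines were alike. On all 8 libraries limma and edgeR each called 420, and neither was run on 1 amount alone. At 5 tags per library 918 of 5630 ends were called, at 30 tags 3 of 11, and in windows of 2000 bp either side 1473 of 7390.

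**Figure D2:**
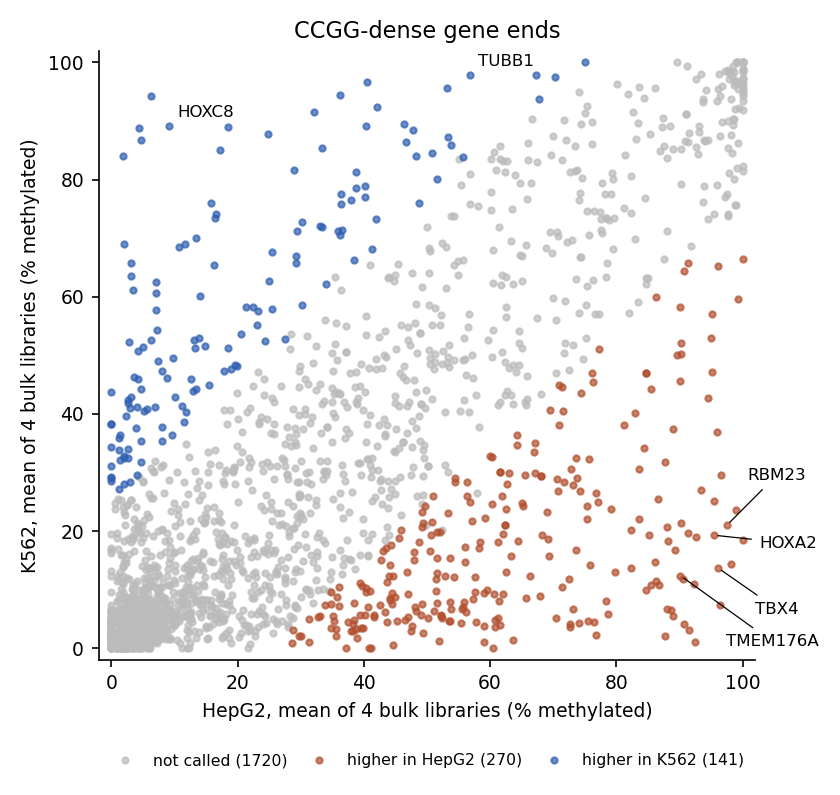
Methylation (percent M tags) of the 2131 tested CCGG-dense gene ends, as the mean of 4 bulk libraries of HepG2 on the horizontal axis and of K562 on the vertical axis, with the 270 ends called higher in HepG2 and the 141 called higher in K562 coloured. TMEM176A, RBM23, TBX4 and HOXA2 lie at the lower right and TUBB1 and HOXC8 at the top.

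Among the gene lists, developmental transcription factors passed the enrichment test at gene ends. Of their 13 measured members (93 listed), 7 were more methylated in HepG2 and 1 in K562, and the HepG2 share exceeded that of the other ends (Fisher's exact test, adjusted p = 0.00931). In windows of 2000 bp either side 16 of 46 were higher in HepG2 (adjusted p = 0.00324), but over whole loci, a setting chosen after the data were seen, 30 of 89 were (adjusted p = 0.120), so the list did not pass there. TBX4, a regulator of hindlimb and lung development (chromosome 17, 61451422 to 61452922), stood at 96.1% ± 4.29 in HepG2 and 13.7% ± 5.55 in K562 (SD, n = 4; limma-moderated adjusted p = 0.000160). PAX8, a thyroid and kidney factor, was at 78.4% against 8.03% and TBX15 at 86.6% against 25.5%. HOX genes, which pattern the body axis, went both ways, with 4 of 13 measured higher in HepG2 and 3 in K562 (Fisher's exact test, adjusted p = 0.523 each). HOXC8 (chromosome 12, 54007985 to 54009485) was at 9.17% ± 10.7 and 89.2% ± 5.27 and HOXB3 at 10.7% and 68.5%, while HOXA2 was at 95.5% and 19.3%.

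The other lists had few measured members and none passed the enrichment test. Of 5 erythroid and blood cell genes, TAL1, a haematopoietic transcription factor, was higher in HepG2 (50.4% against 16.7%) and EPOR, the erythropoietin receptor, in K562 (15.4% against 44.9%). The EPOR call was lost in windows of 2000 bp either side (-20.3 points) and without HepG2 1 ng replicate 1 (-27.2 points, adjusted p = 0.05003). Of 4 hepatocyte genes, EPCAM, an epithelial adhesion molecule rather than a marker of mature hepatocytes, was higher in K562 (20.5% against 53.7%), although in windows of 2000 bp either side its difference turned to 3.76 points the other way. The EPCAM call was also lost with the replicate block (adjusted p = 0.0574) and without HepG2 100 ng replicate 2 (0.0885), HepG2 1 ng replicate 1 (0.05684) or 2 (0.05685), K562 100 ng replicate 1 (0.0877) or K562 1 ng replicate 1 (0.0797) or 2 (0.0803). TAL1, SLC6A6 and KCNQ1OT1 changed direction over whole loci, where PAX8 and EPCAM were not called. Of 4 imprinted genes, KCNQ1OT1, the antisense RNA of an imprinted domain, was at 0% in HepG2 and 28.5% in K562, and without K562 100 ng replicate 2 its difference of -23.2 points fell short of the minimum. Single calls higher in HepG2 were ZNF540 among 8 KRAB zinc finger genes (85.2% against 19.3%), TEX101 among 2 cancer-testis and germline genes (72.6% against 3.57%), L1TD1 among 4 pluripotency genes (47.6% against 3.77%) and WIF1, a secreted Wnt inhibitor, among 6 tumour suppressor genes (83.0% against 40.2%). Of 4 stromal and other cell type genes, COL1A2, a collagen gene, was higher in HepG2 (52.9% against 12.3%) and 1 was higher in K562. Of 7 housekeeping genes 0 were called by the model, 0 had an unadjusted p below 0.05 and limma called 0, with RPLP0 at 3.75% and 2.63% and PPIA at 0% and 0.694%. Clustered protocadherin genes had 0 measured ends of 53. In each list the counts adjusted over the list alone were the same as over all gene ends.

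The methylation level was a few points higher in libraries from 100 ng than in those from 1 ng in both lines, against 19.97 points between the lines. Bulk libraries from 100 ng averaged 57.7% in HepG2 and those from 1 ng 54.1%, and in K562 37.0% and 34.8% (n = 2 each). In HepG2 and K562 the difference was 3.33 and 2.33 points in gene bodies, 3.05 and 2.29 points at gene ends, 3.5996 and 2.47 points at sites with 0 other CCGG sites within 500 bp and 1.01 and 1.23 points at sites with 6 or more. The mean difference of 2.87 points had an exact permutation p of 0.0556, the smallest the design allows, so a p below 0.05 could not be reached. Mitochondrial sites, which serve as a check of digestion, were 9.74% methylated at 100 ng and 5.46% at 1 ng in HepG2, and 9.74% and 6.32% in K562. After correction for that share the differences were 1.61 points in HepG2 and -0.199 in K562 (mean 0.706, exact permutation p = 0.222). The correction can remove too much, since the 10th percentile of K562 1 Mb bins, 4.60%, lay below the mitochondrial share of K562. No gene end was called between the amounts by the quasi-binomial model (0 of 2131), 235 had an unadjusted p below 0.05, and limma on log2 ratios called 20, 14 of them higher at 100 ng. Among those 20, GPATCH4 (47.8 points), DENND6B (43.4) and CSDC2 (41.5, at what is by general knowledge its 3' end) were higher at 100 ng, while PSD2 (-39.3), MAGOH (-37.5) and the proteasome gene PSMB5 (-31.9) were lower.

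Copy number profiles differed between the lines over much of the genome, and many arms were not uniform. HepG2 carried more of chromosomes 2, 16, 17q and 20 and of the proximal part of 14q, and K562 more of 7q and of the proximal part of 22q and less of 9p, 13q and 14q, relative to ESC. As means over whole arms, 20p stood at 1.996 times the ESC level in HepG2 and 0.716 times in K562, arm 20q at 1.90 times in HepG2, and arm 16p at 1.59 times. Arms 2p and 2q were at 1.49 and 1.501 times in HepG2, 17q at 1.46 and 14q at 1.34. In K562, 7q was at 1.53 times, 22q at 1.30 and 1p at 1.29, while 9p was at 0.635 times, 14q at 0.719, 17p at 0.737, 13q at 0.745 and 12p at 0.762. The threshold was passed upward by 11 arms and downward by 0 in HepG2 (2p, 2q, 6p, 6q, 14q, 16p, 16q, 17q, 20p, 20q and 21p). In K562 it was passed upward by 9 (1p, 1q, 5p, 6p, 7q, 18p, 21p, 21q and 22q) and downward by 6 (9p, 12p, 13q, 14q, 17p and 20p). Arm 21p was high in bulk DNA of both HepG2 and K562 (1.54 and 1.36 times) and higher in their cells (1.67 and 1.65). It also had the largest SD of the arms in bulk DNA of each line (log2 0.038 and 0.086), so its level may not reflect copy number. Centring on total autosomal tags shifted log2 values by -0.19 in HepG2 and -0.084 in K562, with 9 arms up and 1 down in HepG2 and 8 up and 8 down in K562. Between the lines, 34 of 40 autosomal arms differed (exact permutation test, adjusted p = 0.0336, 4 libraries per line). Their log2 differences, HepG2 minus K562, ran from -0.620 on 7q to 1.48 on 20p. They were of unlike size, and the smallest was -0.029 on 10p. Differences smaller than the shifts given by centring depend on the centring, so the count is not one of large copy number differences. Counts of covered sites in place of tags put 0 arms of HepG2 and 1 of K562 past the threshold, and 22q of K562 then lay at -0.048 on the log2 scale.

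**Figure D3:**
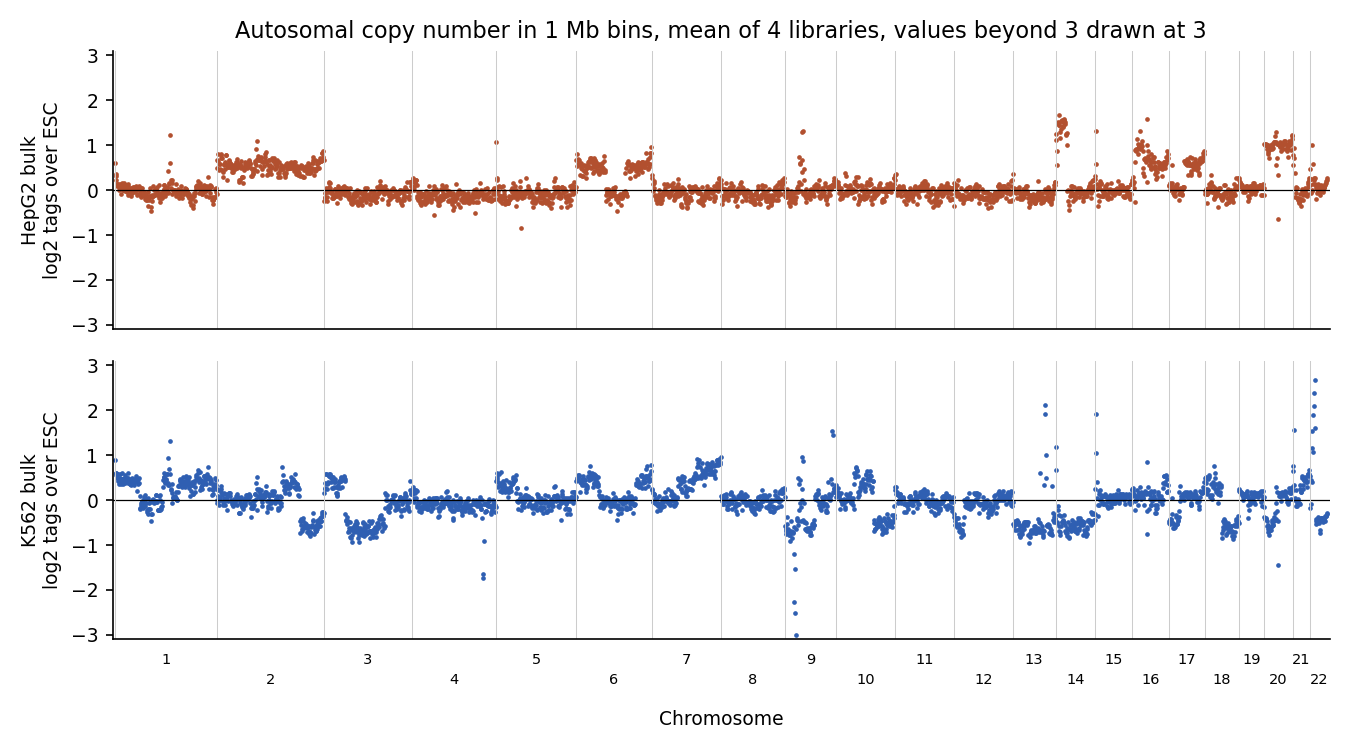
Log2 tag share over ESC along the autosomes in 1 Mb bins (points, mean of 4 bulk libraries) of HepG2 and K562, centred on the median autosomal bin, with values beyond the axis range drawn at its limit. Chromosome 20 lies high in HepG2 along its length, while 22q in K562 has bins far above ESC near the centromere and bins below ESC towards the end.

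Within chromosomes, the BCR and ABL1 regions, whose fusion marks chronic myeloid leukaemia, stood high in K562. The BCR bin (chromosome 22, 23000001 to 24000000) stood at 3.04 times the ESC level in K562 and 1.10 in HepG2, and the ABL1 bin (chromosome 9, 130000001 to 131000000) at 2.90 and 1.08. The neighbouring region of chromosome 22 from 20000001 to 23000000 reached 5.22 times in K562 and 1.19 in HepG2, and that of chromosome 13 from 90000001 to 92000000 with GPC5 4.06 and 0.987. The bin of CDKN2A, a cell cycle inhibitor gene, held 66 tags over the 4 K562 libraries, 0.0124 times the ESC level, against 0.889 in HepG2. On the same arm, the bins with LINGO2 (28000001 to 29000000) and with CAAP1, PLAA, IFT74 and LRRC19 (26000001 to 27000000) stood at 0.176 and 0.208 times in K562 and 0.821 and 0.881 in HepG2, and the bin from 31000001 to 32000000 at 0.118 and 0.902. On chromosome 14, HepG2 lay far above K562 at the bins of STXBP6 (25000001 to 26000000; 2.73 against 0.625) and of SSTR1 and CLEC14A (38000001 to 39000000; 2.77 against 0.622). The BCR, ABL1 and CDKN2A bins each had an exact permutation p of 0.0286 (n = 4, adjusted p = 0.0357), and MYC lay in a bin at 1.02 in HepG2 and 1.05 in K562 (exact permutation p = 0.114). With edgeR, 1511 of 2881 bins differed, 907 higher in HepG2 and 604 in K562. Covered sites in place of tags gave 30 of 2864, and the BCR bin then differed by 0.013 on the log2 scale in the other direction.

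Single cells resembled bulk DNA of their line in methylation and copy number. The level was 51.4% ± 1.35 over the 10 HepG2 cells (49.7% to 53.7%) and 37.1% ± 2.44 over the 10 K562 cells (34.5% to 41.3%), where SD is the spread between cells. All 20 cells were closer to bulk DNA of their own line than to the other, by copy number and by methylation. Copy number correlated with the own line at a median r of 0.814 across bins in HepG2 cells and 0.820 in K562 cells, and with the other line at 0.260 and 0.279. Both profiles share the ESC reference, and cells simulated without copy number changes gave 0.00097 and -0.0024. The median covariance was 0.101 and 0.181, against simulated values of 4.16e-05 and -0.000162. Methylation at gene ends correlated at a median r of 0.786 and 0.738 with the own line and 0.613 and 0.627 with the other. Bins and gene ends are not independent replicates.

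Of 30 called ends taken for their large difference or as list members, 29 had at least 10 pooled tags in the cells of each line, and 25 of these showed the same direction as in bulk DNA, 7 with exact binomial intervals apart. The other 4, all with overlapping intervals, were TMEM275 (40.0% in HepG2 cells and 26.5% in K562 cells), WIF1 (50% and 70%), ZBED4 (23.8% and 19.4%) and KCNQ1OT1 (16.7% and 15.4%). TBX4 was at 97.4% in HepG2 cells and 43.3% in K562 cells, HOXC8 at 15.4% and 70.6%, and TMEM176A at 79.4% (exact binomial interval 62.1 to 91.3) and 19.4% (7.45 to 37.5). BCR stood at 2.67 times the ESC level in K562 cells and 1.28 in HepG2 cells, ABL1 at 2.71 and 1.38. Arm 20p was at 1.73 times in HepG2 cells and 0.872 in K562 cells. CDKN2A was at 0.132 times in K562 cells, against 0.0124 in K562 bulk DNA. Around it, 85 windows of 100 kb on chromosome 9 between 20800001 and 31600000 held 1.16% of the ESC level in K562 bulk DNA (1.03% to 1.25% over 4 libraries) and 11.5% in K562 cells (7.81% to 16.4% over 10 cells, 982 tags). Only chromosome 9 was used. Of the windows that met the rule, 1 further one, on chromosome 10 from 101900001 to 102000000, held 15 tags in K562 bulk DNA, 0.0103 times the ESC level, and 26 in K562 cells. The 10 cells pooled held 6507318 tags, fewer than each K562 bulk library alone, so these 15 and 26 tags are not on the same scale. Pooled tags gave levels of 51.8% in HepG2 cells (exact interval 51.74 to 51.82) and 37.4% in K562 cells (37.39 to 37.47). Fitted as a mixture of the 1 ng bulk profiles, the copy number profile of pooled HepG2 cells gave 11.5% to K562 (bootstrap interval 8.62 to 13.6) and that of pooled K562 cells 13.9% to HepG2 (11.1 to 17.6).

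**Figure D4:**
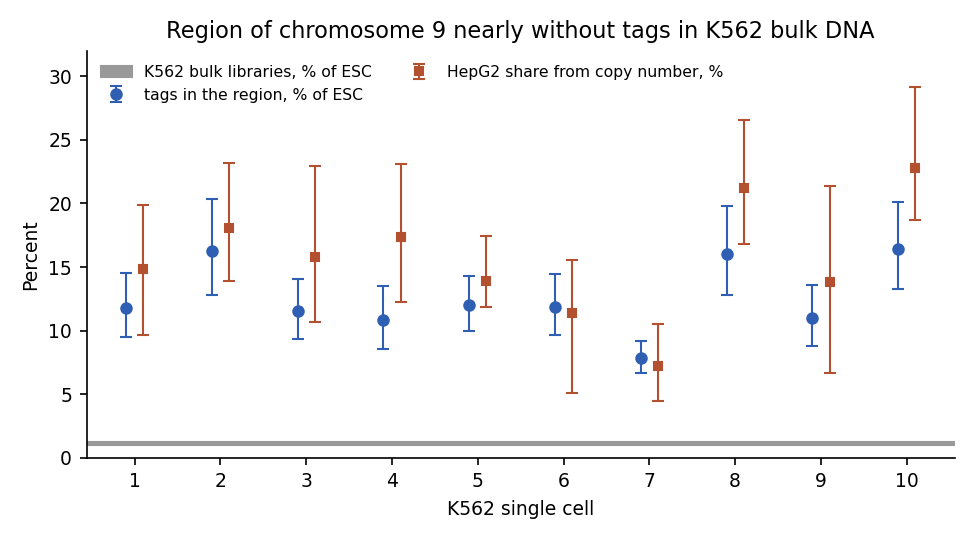
For each of the 10 K562 cells, circles give tags in 85 windows of 100 kb on chromosome 9 as a percent of the ESC level (exact Poisson interval). The windows lie between 20800001 and 31600000, were chosen for few tags in K562 bulk DNA and do not cover that whole stretch. Squares give the HepG2 share fitted from copy number in percent (bootstrap interval). A grey band gives the range of the K562 bulk libraries over the same windows. Bulk libraries lie at 1.03% to 1.25% of ESC and cells at 7.81% to 16.4%.

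The ESC library was more methylated than both cancer lines at many CCGG-dense gene ends. Of 203 ends with at least 50 ESC tags, 37 were at least 50 points above the mean of both lines and 0 as far below, and 27 of the 37 were that far above each line. At 20 ESC tags, 249 of 1792 ends were that far above the mean and 13 below it, and in windows of 2000 bp either side 437 of 2971 and 7. Median levels over the 203 were 59.6% in ESC, 30.3% in HepG2 and 20.6% in K562. PDZK1, a scaffold gene of kidney brush borders, was at 100% in ESC (55 tags, exact binomial interval 93.5 to 100), 2.15% in HepG2 and 2.42% in K562. SLC4A1, the anion exchanger of red blood cells, was at 100%, 1.80% and 10.9%, in a window that by general knowledge of its orientation lies at its 3' end. SLC5A1, an intestinal glucose transporter gene, was at 96.6%, 7.39% and 2.503%, and TTC34 at 94.7%, 2.5% and 5.47%. POU5F1, a pluripotency transcription factor, was at 6.67% in ESC (15 tags, exact binomial interval 0.169 to 31.9), against 88.3% in HepG2 and 64.1% in K562. It had too few tags for the list of 203, and LIN28A, with 0 methylated of 2 ESC tags, gives no level at this depth. NANOG and DPPA4 had no qualifying gene end. There is 1 ESC library, so these differences have no replicate check. Its mitochondrial sites, the check of digestion, were 11.8% methylated, above each HepG2 and K562 bulk library (5.38% to 10.8%). Corrected for that share, the ESC level was 95.6%.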

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

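The tests of tags of the other line, of incomplete digestion in cells, of other sites covered in cells and of the number and fitted share of foreign tags against tag number, and the shares with each cell left out, were chosen only after the result was seen. The tests of read placement by the alignment, of the methylation of the tags and of the share of foreign tags against tag number were chosen before their values were seen.

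Single cell libraries held tags from regions that bulk DNA of their line nearly lacked: 11.5% of the ESC level in K562 cells against 1.16% in bulk over 85 windows around CDKN2A (1 further window, on chromosome 10, was left out), and 15.5% against 2.47% in HepG2 over 3 windows with 48 cell tags. The values argue against reads of other K562 loci placed there by the alignment, since the tags followed HepG2 DNA from site to site: they were 79.2% methylated at the 159 sites at or above 50% in HepG2 bulk DNA and 12.4% at the 429 sites below, a difference of 66.8 points (bootstrap interval over windows 58.5 to 74.6) against 72.5 in HepG2 bulk DNA. In K562 cells the tags were 30.3% methylated (Wilson interval 27.3 to 33.5), 2.31 points above HepG2 bulk DNA at the same sites (-0.724 to 5.54), whereas ESC DNA stood at 96.4%, so DNA from HepG2 libraries may be a source. In K562 cells the number of foreign tags rose with the tag number of the cell (rho = 0.857, permutation p = 0.00242, adjusted 0.0218; r = 0.933, permutation p = 0.00065, adjusted 0.00381; 0.719 and 0.739 without the 2 farthest cells), which argues against a fixed number per library as the whole source. The share of foreign tags fell with tag number by r = -0.793 (permutation p = 0.00127, adjusted 0.00381) but not past the threshold by rho = -0.60 (permutation p = 0.0733, adjusted 0.110), the test set before, and the share fitted from copy number was lower in cells with more tags (rho = -0.818, permutation p = 0.00597, adjusted 0.0269 in K562; rho = -0.770, permutation p = 0.0131, adjusted 0.0393 in HepG2), so a fixed number as a part of the source stays open, and no biological explanation was tested.

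The methylation levels of the lines lay closer together in cells than in 1 ng bulk DNA, 14.4 against 19.3 points. The values argue against incomplete digestion as the whole cause, since it would raise both lines. Pooled HepG2 cells lay -2.34 points from 1 ng bulk DNA and K562 cells 2.61. Incomplete digestion as a part of the rise in K562 cells stays open. Mitochondrial sites of K562 cell 7 were 23.6% methylated (next 8.19%), and without that cell the pooled K562 level was 36.7%, against 37.4%. The values also argue against other covered sites, since 98.9% of the loss was kept on sites with a tag in all 8 bulk libraries. There the gap was 19.4 points in bulk and 14.5 in cells. The pooled levels would need 12.1% of tags from the other line in HepG2 cells and 13.5% in K562 cells, and copy number profiles gave 11.5% (bootstrap interval 8.62 to 13.6) and 13.9% (11.1 to 17.6), against 2.96% and -1.23% for 100 ng bulk DNA, but without K562 cell 7 the K562 level would need 9.95% against a fitted 15.95% (12.9 to 20.1), and over the K562 cells methylation had r = 0.0415 with the share of foreign tags. Tags of the other line as the whole cause cannot be told apart from others, since the match in K562 rests on that cell; no biological explanation was tested, and a difference between cultured cells and bulk DNA stays open.

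Mitochondrial sites, outside the nuclear measurement, were 7.60% methylated in HepG2 bulk DNA and 8.03% in K562 bulk DNA.

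Some single libraries stood apart from the others of their group by the gap to the nearest library, which chance gives in about 1 of 20 groups. Past that limit were 1 of 40 arms in HepG2 bulk DNA, 8 in K562 bulk DNA, 3 in HepG2 cells and 6 in K562 cells. In HepG2, bulk 1 ng replicate 1 was highest on 10q (log2 0.0406). K562 bulk 100 ng replicate 2 was lowest on 9q (0.0999), 10q (-0.0413), 14q (-0.506), 15q (0.0485), 16p (0.0915), 20q (-0.00728) and 21q (0.373), and 100 ng replicate 1 was highest on 12q (0.0515). HepG2 cell 5 was highest on 3p (0.0921, next -0.0927), cell 4 highest on 9q (0.258, next 0.0555) and cell 8 lowest on 4p (-0.123, next -0.0258). K562 cell 6 was lowest on 6q (-0.161, next 0.200). K562 cell 10 was highest on 17q (0.374), 19p (0.426), 19q (0.305) and 20q (0.350) and lowest on 21q (-0.192, next 0.183). HepG2 cell 1 held 1248899 tags (next 825066), and HepG2 cell 4 had the highest share fitted to the other line, 22.2% (next 14.7%). K562 cell 7 held 1515793 tags on 893513 sites (next 580624 sites), its mitochondrial sites were 23.6% methylated (next 8.19%), and its corrected level was 21.1% (next 31.0%).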

How the results depend on the processing

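The runs on whole loci, on 1 Mb bins for input amount, on tags per observed site, with mitochondrial correction, on shared sites for single cells and without K562 cell 7 were chosen only after the result was seen. Of 1458 alternatives to 130 results, 1150 were counted as the same, 155 were weaker, 147 moved and 6 reversed. Tests, named genes and named bins were the same if they kept direction and side of the threshold. For some tests the design fixed this label. With 1 library left out, the exact permutation p cannot fall below 0.0571, so 56 runs on site classes and 8 on the level had to be weaker. For the input level no p below 0.05 can be reached, so runs that kept the sign were the same, even at 0.706 points after mitochondrial correction. For these runs the tally does not measure robustness. Counts were the same within a fixed factor of the main count, and arms and single cell levels within the SD of the main value. Named arms that moved kept their direction. Of 2131 gene ends 411 differed between the lines, against 918 at 5 tags, 3 at 30 tags, 1473 in windows of 2000 bp, 4870 over whole loci and 0 with the 100 ng or the 1 ng libraries alone. These settings test other numbers of regions (5630, 11, 7390, 17684, 3453 and 3394). The last pair uses 4 libraries, where the calls of all 30 named genes were lost whatever the size of their difference. Of 1 Mb bins 2429 differed in methylation, against 548 of 599 bins of 5 Mb, which are fewer. For input amount, limma called 20 gene ends and the 1 Mb bins without a minimum difference gave 1760. Copy number calls were 1511, against 308 of 601 bins of 5 Mb, 30 with covered sites and 2336 without a minimum log2 difference. Arms past the threshold numbered 26, against 1 with covered sites, which count a site the same at any number of tags. ESC gene ends numbered 37, against 262 at 20 tags and 444 in windows of 2000 bp. With each list tested per direction, 1 of 22 list tests passed, against 5 of 24 in windows of 2000 bp and 8 of 24 over whole loci and 9 of 24 over whole loci that do not overlap, and the list that passed at gene ends, developmental transcription factors, passed in neither run over whole loci. Reversed were arm 22q of K562 with covered sites (-0.0479 on the log2 scale), the copy number bin of BCR with covered sites (0.013), SLC6A6 (3.79 points), TAL1 (-20.5) and KCNQ1OT1 (17.69) over whole loci, and EPCAM in the 2000 bp windows (3.76). For these, for the limma calls and for lists, the cause was not tested.

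With each bulk library left out in turn, gene end calls ranged from 356 to 453, bins from 2395 to 2472, copy number bins from 1509 to 1517, arms stayed at 26, and the input difference ranged from 2.74 to 2.998 points. The level difference ranged from 19.3 to 20.6 points with an exact permutation p of 0.0571, the smallest that 3 against 4 can give. Replicate numbers did not pair the libraries (correlations of deviations -0.036 to 0.065). With the replicate block, gene end calls were 357, all among the 411, methylation bins 2429, copy number bins 1513, input calls 0 (0 without it) and the input difference had an exact permutation p of 0.125. Without K562 cell 7 the mean level of K562 cells was 36.9%. A reference of CCGG sites in the genome was not run, since no genome was used, and tags per site seen in any library took its place. Depth left 2131 of 11531 dense ends with 10 tags in each library.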

Other observations

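The runs over whole gene loci and 1 Mb bins, the digestion test for input amount and the regroupings of libraries were chosen only after the result was seen, and the test of other sites covered at 1 ng was chosen before.

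Over whole gene loci with 1000 bp either side, hepatocyte genes were called higher in HepG2 more often than other loci, and a mixed list of erythroid and blood cell genes higher in K562. Of 32 measured hepatocyte genes, 18 were more methylated in HepG2 and 0 in K562 (Fisher's exact test, adjusted p = 0.00124). TTR, the thyroid hormone carrier made by liver (chromosome 18, 31591877 to 31598821), stood at 91.1% ± 4.16 in HepG2 and 4.36% ± 2.10 in K562 (SD, n = 4), and APOB, the main apolipoprotein of low-density lipoprotein, at 79.8% ± 4.496 and 6.89% ± 0.255. HNF4A, a liver transcription factor, was at 73.4% and 16.6%, NR1H4, the bile acid receptor, at 89.0% and 7.15%, and AMBP at 85.2% and 9.24%. Of 35 erythroid and blood cell genes, 9 were higher in K562 (adjusted p = 1.25e-06) and 2 in HepG2 (adjusted p = 0.0188, fewer than among other loci). RHAG, a red cell membrane protein (chromosome 6, 49605175 to 49636839), stood at 49.9% ± 5.64 in HepG2 and 93.4% ± 3.13 in K562. The blood cell factors NFE2 (71.5% and 9.36%) and LYL1 (72.0% and 15.1%) were higher in HepG2.

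Gene clusters also differed over whole loci. Of 41 clustered protocadherin genes, which encode neuronal adhesion molecules and overlap one another, 36 were higher in HepG2, with PCDHGA3 at 60.03% and 14.4%. Overlapping loci share tags, which makes Fisher's p too small, and among loci that do not overlap 6 of 6 protocadherin genes were higher in HepG2 (Fisher's exact test, adjusted p = 0.00221). Loci that do not overlap can still be neighbours in a cluster and are then not independent. Fisher's p can therefore be too small for the protocadherin, HOX and KRAB zinc finger lists in each setting. Of 124 KRAB zinc finger genes, 60 were higher in HepG2 (adjusted p = 2.01e-07), with ZNF382 at 89.8% and 6.69%. HOX genes were higher in HepG2 at 10 loci and in K562 at 7 (adjusted p = 0.000139 for K562), with HOXA6 at 95.8% and 11.98% and HOXB8 at 31.3% and 91.3%. Of 32 imprinted genes 17 were higher in HepG2 (adjusted p = 0.00278), with SGCE at 91.3% and 3.85% and its neighbour PEG10 at 76.7% and 9.10%, and of 22 pluripotency genes 11 (adjusted p = 0.0352). Among loci that do not overlap, higher in HepG2 were 16 of 27 hepatocyte (adjusted p = 0.00287), 52 of 112 KRAB zinc finger (9.74e-05), 13 of 25 imprinted (0.0315) and 11 of 21 pluripotency genes (0.0333), and higher in K562 8 of 31 erythroid and blood cell (2.58e-05) and 6 of 22 HOX genes (0.000142). There 1 of 31 erythroid and blood cell (0.00654) and 1 of 24 housekeeping genes (0.0315) were higher in HepG2, fewer than among other loci. Genes were picked after their values were seen. In the 2000 bp windows the protocadherin (9 of 10, adjusted p = 5.18e-06), KRAB zinc finger (23 of 62, 8.26e-05), developmental transcription factor (16 of 46, 0.00324), tumour suppressor (9 of 23, 0.0182) and pluripotency lists (6 of 14, 0.044) were higher in HepG2 by Fisher's exact test.

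Methylation was higher at 100 ng than at 1 ng in both lines, and over 1 Mb bins 1752 of 2875 were higher at 100 ng and 8 lower, with a median difference of 2.38 points. Correction by mitochondrial sites removed 54.4% of the difference in HepG2 and 109% in K562. The correction can remove too much, since K562 mitochondrial sites (8.03% in bulk DNA) were more methylated than the 10th percentile of K562 1 Mb bins (4.60%). Incomplete HpaII digestion may account for part of the difference, but the correction does not give the size of that part. On sites shared by the 8 bulk libraries, 76.6% of the difference was kept in HepG2 and 74.6% in K562, so other sites covered at 1 ng may add to it. Neither can be told apart as the whole cause, since neither value passed the bound set for it in both lines and each line has 2 libraries per amount. The amount of DNA itself stays open, as it was not varied apart from these.

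The models could take 34 splits of the 8 bulk libraries into 4 and 4, and the real split alone gave its count. Gene ends numbered 411 in 1 split (highest other 0), methylation bins 2429 in 1 (0) and copy number bins 1511 in 1 (0). All other splits mix the lines, which widens the spread within their groups and makes calls unlikely. The real split thus ranks first of 34, but the counts of 0 do not exclude chance. For input amount the real count was 0 gene ends, which all 34 splits must reach (highest other 0), so the splits say nothing about chance there.

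Across 2737 autosomal 1 Mb bins, which are not independent, log2 copy number over ESC correlated with methylation minus ESC at r = 0.231 in HepG2 and 0.151 in K562 (rho 0.379 and 0.269). Over the 10 HepG2 cells, methylation level and tag number had r = 0.775 (permutation p = 0.0054, adjusted 0.0121) and rho = 0.745 (permutation p = 0.0174, adjusted 0.0393). Without the 2 farthest cells r was 0.264 and rho 0.50, so the linear relation rests on those cells. Over the 10 K562 cells the same relation had r = 0.258 (permutation p = 0.524) and rho = 0.0424 (permutation p = 0.919). Over the 10 K562 cells, methylation had r = 0.0415 and rho = 0.20 (permutation p = 0.584) with the share of foreign tags, and r = 0.391 (permutation p = 0.269) and rho = 0.60 (permutation p = 0.0734) with the mitochondrial methylated share. The share of foreign tags in the windows lacking in K562 bulk DNA had r = -0.793 (permutation p = 0.00127, adjusted 0.00381) and rho = -0.60 (permutation p = 0.0733, adjusted 0.110) with tag number over the 10 K562 cells, and -0.705 and -0.262 without the 2 farthest. The share fitted from copy number had r = -0.819 (permutation p = 0.00112, adjusted 0.00381) in K562 cells and -0.649 (permutation p = 0.0738, adjusted 0.133) in HepG2 cells with tag number, and -0.802 and -0.70 without the 2 farthest.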
